A study of Oryctolagus cuniculus with 12 samples.

How the data were processed

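RNA of the uterine body was sequenced in 12 New Zealand White rabbits, 3 in each of the groups Control, LPS, CsA and LPS+CsA. The labels describe separate animals, 1 library each, so the p-values measure differences against the variation between animals. Estrus and ovulation had been synchronised, per the labels, and 1 µg of total RNA entered each Illumina library.

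The authors aligned the reads with TopHat2 and made FPKM values with Cufflinks and Cuffnorm, per the submitters' processing notes; versions and the genome build are not given in the sources used here. The deposited FPKM tables hold 17301 genes per library, 15521 with an Ensembl identifier and 1780 loci that the authors assembled. The deposited comparison tables hold 437 identifiers in 3 tables: LPS against Control, LPS+CsA against LPS, and the genes with opposite directions in both. Per the file headers, the tables of LPS against Control and of LPS+CsA against LPS hold a read count and an FPKM value per library, a log2 fold change and a p-value. From the table of opposite directions, FPKM values and the log2 fold change of each comparison were used. The authors' p-values are unadjusted in size, the largest being 0.0492 and 0.0488, and the smallest absolute log2 fold change in the authors' LPS table is 1.00. The deposited count columns cover 9 libraries and hold only the listed genes, so no library total follows from them. Of 960, 1698 and 1404 FPKM values held by both kinds of file, 3, 0 and 1 differed at a relative tolerance of 0.0001. Annotation text, symbols and gene ontology terms were those the authors deposited in the comparison tables.

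Gene symbols came only from the authors' tables, which pair 303 of the 437 identifiers with a symbol. No identifier of the series was found in the reference table of 38822 genes, so genes outside those tables have no symbol here. TNF, IL1B, IL6, PTGS2, NFKBIA, TLR4, CD14, IL2, IL2RA and IFNG, which were to be given in every comparison, are not analysed here for that reason, and CXCL8 was the only such gene with a symbol. The symbols were thus chosen by the authors on these samples. Of the 12794 genes tested, 256 had a symbol.

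Groups, comparisons, tests, gene lists and alternatives were fixed before the data were examined. Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested. A model with a mean per group was fitted over all libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance, two-sided, and Benjamini-Hochberg adjustment at 5% over the genes of a comparison. The 6 comparisons were LPS against Control, LPS+CsA against LPS, CsA against Control, LPS+CsA against Control, LPS+CsA against CsA, and the interaction. Differences are log2 differences with the standard error from limma; FPKM values are means with the SD over 3 animals. Other tools were jsonlite 2.0.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

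The named genes followed a rule. Where no gene passed, the 5 genes with a symbol and the smallest p in each direction were named as not passing, with up to 4 members of each list described, the 5 highest and 5 lowest of each deposited table, CXCL8, and the 2 highest and 2 lowest identifiers without a symbol in LPS against Control. Any other gene is said to have been chosen after its values were seen, which also holds for ISG15, HBB2, ALAS2 and PPIA. Of 37 gene lists, 17 had no measured member with a symbol and 14 had 1 or 2. The 6 with 3 or more were tested: interferon-stimulated, plasma cell, chemokine, NF-kB feedback, neutrophil, and antimicrobial and acute phase genes. At most 18.2% of a list's genes had a symbol, so each median covers a small part of its list. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 6 lists. The last pair of lists shares S100A8, S100A9 and S100A12.

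The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios rescaling, quantile normalization, a fit on the compared groups alone, no variance trend, array weights, the replicate number as a block, and leaving out each library. Robust variances, leaving out the 2 libraries of lowest weight, and an unadjusted p under 0.05 with a 2-fold change were added after seeing the data. Replicate numbers are not said to pair animals and were not in the model. The test was checked on simulated data with 200 changed genes, in which genes were independent and normally distributed. Their spreads were drawn from the variance prior that limma had fitted to the real genes. Unlisted reads, sequences and library totals are not analysed here.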

Results

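The series measured messenger RNA in the uterine body of New Zealand White rabbits by RNA sequencing. There were 4 groups of 3 animals, 12 libraries in all. Animals had received saline (Control), 4 mg/kg of lipopolysaccharide, the outer-membrane component of Gram-negative bacteria that sets off innate immune responses (LPS), 20 mg/kg of cyclosporine A, an inhibitor of calcineurin and of T cell activation (CsA), or both (LPS+CsA). The tissue was taken after 3 h of treatment. The labels differ on the route, naming an infusion into the uterus in one place and into the vagina in another. They also differ on the vehicle and on when CsA was injected relative to the infusion, so the dose that reached the tissue before sampling is not fixed by the labels. Each library held FPKM values, reads scaled to transcript length and library size, for 17301 genes, of which 11945 to 12398 reached 1 FPKM. The FPKM sums lay between 579986 and 747163, and the 10 highest genes held between 15.4% and 20.3% of the sum. Read totals are not known. In the 9 libraries for which the authors' tables give read counts, the counts behind 1 FPKM lay between 0.953 and 1.015 of the mean over the libraries of a table (geometric mean per gene, median over listed genes), and the median count of a listed gene lay between 76 and 118. Whether these counts are raw or scaled is not given in the sources used here, so the ratio carries no firm information on read depth.

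The groups overlapped in their overall profiles. Over the 12794 genes tested, the median correlation between libraries was 0.960 within groups and 0.959 between groups, across genes, which are not independent replicates. The first component held 19.9% of the variance and was led by CsA 2, and the second held 17.1% and was led by LPS 1. The 4 groups accounted for 30.7% of the squared distance between libraries, against a median of 27.1% when the labels were shuffled (permutation p = 0.117, one-sided, 10000 shuffles).

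**Figure D1:**
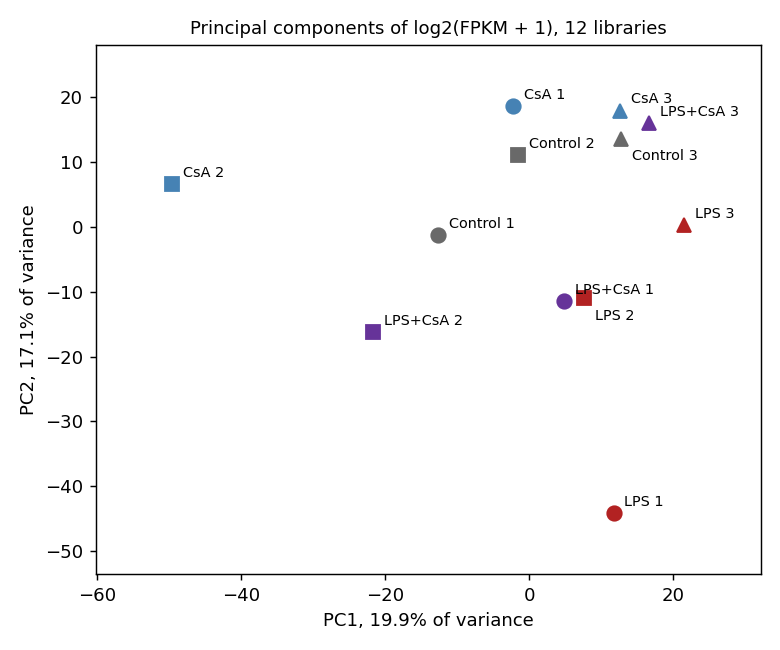
Scores of the 12 libraries on the first (x axis, 19.9% of variance) and second (y axis, 17.1%) principal component of log2(FPKM + 1), both without units. Each point is an animal, colours are the 4 groups and shapes the animal numbers; CsA 2 at -49.5 on the first component and LPS 1 at -44.2 on the second stand farthest out.

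The first comparison asked how the uterine body responded to LPS. TUBE1, epsilon-tubulin of the centriole (ENSOCUG00000009644), stood at 32.6 ± 7.31 FPKM in Control and 9.17 ± 2.14 in LPS (SD, n = 3), with no overlap between the groups. KRT75, a type II keratin, stood at 23.0 ± 7.91 and 5.69 ± 0.846 FPKM, and TRAC, the constant chain of the T cell receptor alpha, at 3.06 ± 0.862 and 0.909 ± 0.238. On the other side MEDAG, a promoter of adipocyte differentiation, stood at 18.6 ± 4.82 FPKM in Control and 46.2 ± 9.71 in LPS, and RASGRF2, an activator of Ras proteins, at 0.942 ± 0.0685 and 2.31 ± 0.742. None of these differences passed the test across all genes (limma, two-sided, adjusted p = 0.75 for each of the 5). By the authors' counts TRAC rested on few reads, at 44, 36 and 51 in Control and 8, 12 and 14 in LPS.

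Of the 12794 genes, limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.405. An unadjusted p under 0.05 was reached by 839 genes, 525 higher and 314 lower in LPS, where 639.7 would be expected if no gene differed. With a change of at least 2-fold there were 111, 62 higher and 49 lower. Among genes with a symbol, the others nearest to the threshold on the higher side were ZFP62, with a log2 difference of 0.82 ± 0.20 (SE), C20orf85 at 2.74 ± 0.75 and CPXM2 at 1.77 ± 0.56. On the lower side they were NECAB3 at -0.97 ± 0.25 and CRYM, a thyroid hormone binding protein, at -1.49 ± 0.40. Each had an adjusted p of 0.75 in limma. CPXM2 was at 1.05 without LPS 1 and CRYM at -0.97 without Control 2, and with a pseudocount of 0.1 C20orf85 was at 5.01 and NECAB3 at -1.64. Groups did not overlap for 1748 genes (13.7%, where chance gives 10%). On simulated groups of the same size, with independent genes, the test recovered 73.1% of 2-fold and 92.5% of 4-fold changes made on the log2(FPKM + 1) scale. Real genes are not independent, so this share and those of the later comparisons need not hold for them. Without LPS 1 the 839 genes became 432, and limma called 1 gene, ENSOCUG00000025431. Without LPS+CsA 3 it also called 1, ENSOCUG00000009991, at 2.73, 3.64 and 4.56 FPKM in Control and at most 0.177 in LPS, a gene singled out after its values were seen.

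Genes without a symbol gave the widest differences. ENSOCUG00000025431 stood at 0.729, 221 and 197 FPKM in LPS 1, LPS 2 and LPS 3 and under 1.35 FPKM in the 9 other libraries. An assembled locus, Rabbit_newGene_6971, was listed at 0 in the 3 Control libraries and in LPS 1, and at 212 and 224 FPKM in LPS 2 and LPS 3. ENSOCUG00000024462 and ENSOCUG00000022443 stood at 78.7 to 181 FPKM and 71.0 to 145 FPKM in Control, and in LPS at 89.4 and 77.2 FPKM in LPS 2 but at 0.260, 0.267, 0 and 0 in LPS 1 and LPS 3. Of the 10363 genes at 5 FPKM or more in some library, 122 are listed at 0 in another.

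The interferon-stimulated and plasma cell genes with a symbol stood lower in LPS than in Control by value. All 8 measured interferon-stimulated genes, the effectors of antiviral defence, stood below Control, with a median log2 difference of -1.17. MX2 was at 87.4 ± 54.1 FPKM in Control and 25.2 ± 6.84 in LPS (SD, n = 3), IFI44L at 46.3 ± 15.7 and 23.1 ± 9.36, IFIT3 at 8.30 ± 3.05 and 3.34 ± 1.09, and OAS2 at 5.34 ± 3.41 and 1.51 ± 0.518. The 3 measured plasma cell genes also stood below Control, with a median of -1.23: JCHAIN, the chain that joins polymeric immunoglobulins, was at 60.9 ± 51.6 and 18.9 ± 3.75 FPKM, and MZB1, a chaperone of antibody-secreting cells, at 5.37 ± 3.59 and 1.47 ± 0.391. Both lists passed camera with its preset correlation (adjusted p = 0.000312 and 0.00411). Neither passed with an estimated correlation, where the adjusted p was 0.487 for the interferon list and 0.152 for the plasma cell list. None of the 8 and 3 genes was called over all genes tested. MZB1 and JCHAIN were 2 plasma cell genes that passed adjusted over the list alone, and 0 interferon-stimulated genes did. All 8 interferon-stimulated genes, and JCHAIN and MZB1, have a symbol because the authors list them as lower in LPS in this same comparison. The list tests and the counts thus repeat that selection and are not independent evidence of direction. By the authors' counts MZB1 rested on few reads, at 20, 28 and 72 in Control and 7, 12 and 13 in LPS. Control 3 carried much of the plasma cell difference, with JCHAIN at 120.4 FPKM against 31.1 and 31.0 in Control 1 and Control 2. Without Control 3 the median of the plasma cell list was -0.80, and JCHAIN differed by -0.71 in place of -1.35. The 2 measured red blood cell genes were chosen after their values were seen and are also listed by the authors as lower in LPS. They stood the same way by value: HBB2 at 265 ± 94.0 and 120.0 ± 10.1 FPKM in Control and LPS, and ALAS2 at 3.86 ± 1.69 and 1.76 ± 0.295 (SD, n = 3). The limma adjusted p was 0.75 for both.

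Of the genes that LPS is known to induce through Toll-like receptors, few had a symbol, and TNF, IL1B, IL6 and NFKBIA are not analysed here. The 4 chemokines and 5 NF-kB feedback genes that could be named are those the authors list as higher in LPS+CsA than in LPS, a choice that favours low values in LPS. CXCL8, the neutrophil-attracting chemokine, was at 1.77 ± 2.72 FPKM in Control and 0.752 ± 0.176 in LPS (SD, n = 3), a log2 difference of -0.22 ± 0.67 (SE, limma adjusted p = 0.966) whose sign turned to 0.21 with a pseudocount of 0.1 and to 0.55 without Control 3. The 4 chemokines had a median of -0.44 (camera adjusted p = 0.289). The list passed without Control 1 or Control 2 (0.0335 and 0.0499), and its median turned to 0.33 without Control 3. CXCL10 stood at 50.01 FPKM in Control 3 against 2.15 and 5.39 in Control 1 and Control 2, CX3CL1 at 39.8 against 3.78 and 3.56, and CXCL11 at 3.66 against 0.475 and 0.950. The 5 NF-kB feedback genes had a median of -0.25 (camera adjusted p = 0.941), which turned to 0.34 without Control 3, as did TNFAIP2 to 0.04, and was -0.63 without Control 1. TNFAIP8 was near 0 FPKM in Control and at 2.13, 1.44 and 0.00109 FPKM in LPS, so that no fold is given. The others named were TNFAIP3 at -0.45 ± 0.36, TNFAIP2 at -0.44 ± 0.53 and BCL3 at 0.25 ± 0.36 (SE), with TNFAIP3 at -0.05 without Control 3 and BCL3 at 0.06 without Control 1. S100A8, S100A9 and S100A12, calcium-binding proteins of neutrophils, had a median of 0.40, and the antimicrobial list, which holds the same 3 genes with DMBT1, CHI3L1 and ACOD1, had 0.32 (camera adjusted p = 0.941 for both). Without Control 1 the neutrophil median turned to -0.53 and the antimicrobial median to -0.54, and without Control 3 they were 1.62 and 1.32, none past camera. DMBT1 was at 0.88 ± 0.61 and CHI3L1 at -0.61 ± 0.45, the former at 0.53 without LPS 1 and the latter at -1.22 with a pseudocount of 0.1. In these 4 lists 0 genes passed adjusted over the list alone.

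**Figure D2:**
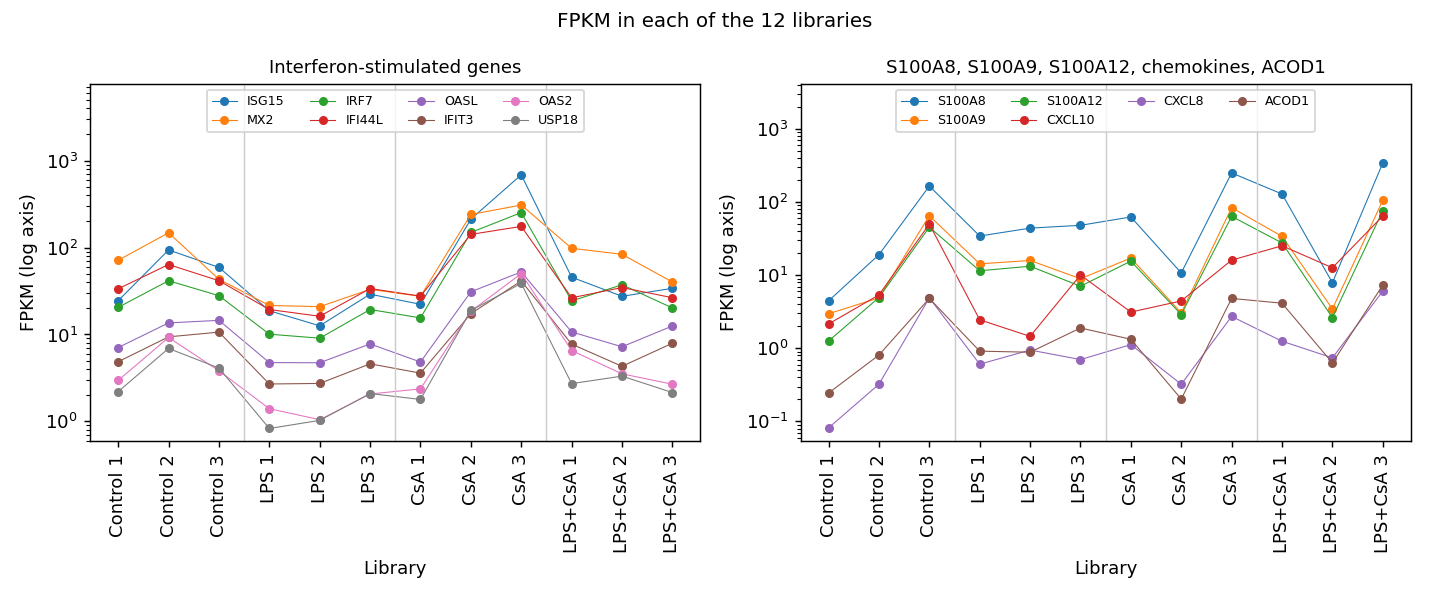
FPKM (y axis, log scale) of named genes in each of the 12 libraries (x axis), with interferon-stimulated genes on the left and S100A8, S100A9, S100A12, CXCL10, CXCL8 and ACOD1 on the right; points of a gene are joined only to guide the eye. ISG15 reached 212 and 686 FPKM in CsA 2 and CsA 3 but 22.3 in CsA 1, and S100A8 stood at 166, 251 and 344 FPKM in Control 3, CsA 3 and LPS+CsA 3.

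The authors' deposited table of LPS against Control lists 283 genes, 160 higher and 123 lower in LPS. In that table the highest fold changes with a symbol belonged to FIGNL1 (log2 fold change 7.83), ZNF770 (4.18), FOXJ1, the master regulator of motile cilia (3.69), CDC20B (3.27) and KCNIP1 (3.00). The lowest in the authors' deposited table belonged to GREM1, an antagonist of bone morphogenetic proteins (-2.36), IBSP (-2.35), CKMT2 (-2.08), SLC5A12 (-2.02) and CXCL10 (-1.98). FIGNL1 was listed at or near 0 in the 3 Control libraries, at most 0.00195 FPKM, so its fold has no firm denominator. FOXJ1 rested on LPS 2, at 0.538, 11.5 and 2.86 FPKM in LPS 1, LPS 2 and LPS 3, and KCNIP1 on LPS 1, at 28.4, 7.32 and 2.18 FPKM. The lower value of CKMT2 rested on Control 1, at 2.85, 0.0513 and 0.121 FPKM in Control against 0.327, 0.155 and 0.310 in LPS, and its difference in limma turned from -0.39 to 0.22 without Control 1. That of CXCL10 rested on Control 3 and went from -1.15 to 0.02 without Control 3. The largest p-value in the authors' deposited table was 0.0492. At least 42 of its 283 genes, 27 higher and 15 lower, would pass a Benjamini-Hochberg bound of 0.05 over the 17301 genes. Genes outside the table could not be ranked, so this is a lower bound. A deposited header names edgeR for the authors' fold changes. This count and those by limma on log2(FPKM + 1) thus rest on unlike methods. Of the 249 listed genes that were tested here, 249 had the same sign in the limma fit, 112 an unadjusted p under 0.05 and 0 an adjusted p under 0.05. The groups did not overlap for 138 of them. The table was made from the same libraries, so the shared signs are not a second observation.

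The next comparison, named in the title of the series, asked what CsA did in LPS-infused animals. LSM10, a subunit of the particle that processes histone messenger RNA, stood at 16.9 ± 2.88 FPKM in LPS and 2.39 ± 1.25 in LPS+CsA (SD, n = 3), the gene with a symbol nearest to the threshold (log2 difference -2.45 ± 0.37, SE; limma adjusted p = 0.458). Its counts were low, at 34 to 56 and 4 to 8 reads in the authors' deposited table. TRAC stood at 0.909 ± 0.238 and 4.54 ± 1.98 FPKM, KRT75 at 5.69 ± 0.846 and 22.6 ± 8.52, SOX9, a transcription factor of gland epithelium, at 2.49 ± 0.490 and 5.97 ± 1.35, and TTC39C at 4.93 ± 0.652 and 9.82 ± 1.68. None passed (limma adjusted p = 0.585 for these 4 and for TMEM139). The counts of TRAC were low as well, at 8, 12 and 14 reads in LPS and 65, 73 and 32 in LPS+CsA. WNT11, a secreted Wnt ligand, stood at 3.10 ± 0.582 FPKM in LPS and 1.02 ± 0.0958 in LPS+CsA, with an adjusted p of 0.587 in limma.

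Limma called 0 of the 12794 genes, with a smallest adjusted p of 0.458. An unadjusted p under 0.05 was reached by 1031 genes, 620 higher and 411 lower in LPS+CsA, and 93 of them, 60 higher and 33 lower, had a change of at least 2-fold. On the lower side MFSD9 (-1.05 ± 0.31, SE), GYG1, the primer of glycogen synthesis (-0.89 ± 0.28), and ABCA6, a lipid transporter (-1.02 ± 0.33), were also nearest to the threshold among genes with a symbol. Their limma adjusted p lay between 0.587 and 0.595. Without LPS 1 GYG1 was at -0.49 and ABCA6 at -0.66. Groups did not overlap for 2005 genes (15.7%, where chance gives 10%). The test recovered 71.6% of 2-fold and 88.1% of 4-fold changes on simulated groups. Without LPS 1 the 1031 genes became 661, and limma called 1 gene, ENSOCUG00000025431.

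**Figure D3:**
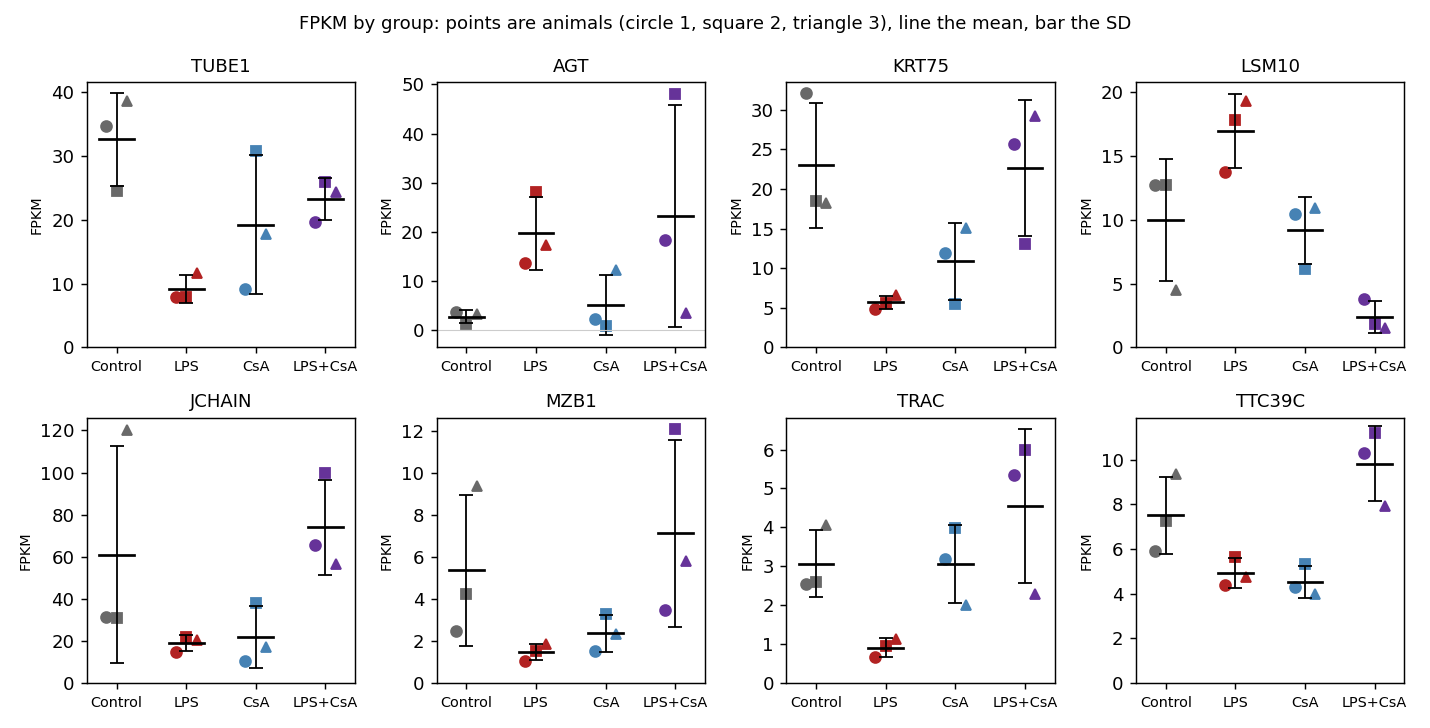
FPKM (y axis) of 8 genes in the 4 groups (x axis); points are animals, horizontal lines the mean and bars the SD (n = 3). JCHAIN stood at 18.9 ± 3.75 FPKM in LPS and 73.9 ± 22.7 in LPS+CsA, and LSM10 at 16.9 ± 2.88 and 2.39 ± 1.25.

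Plasma cell, chemokine and NF-kB feedback genes stood higher in LPS+CsA than in LPS. JCHAIN was at 18.9 ± 3.75 FPKM in LPS and 73.9 ± 22.7 in LPS+CsA (SD, n = 3), MZB1 at 1.47 ± 0.391 and 7.11 ± 4.45, and DERL3, a factor of protein quality control in the endoplasmic reticulum, at 2.12 ± 1.29 and 7.22 ± 2.43. The median over these 3 plasma cell genes was 1.58 on the log2 scale. MZB1 rested on few reads, at 7, 12 and 13 in LPS and 24, 89 and 45 in LPS+CsA. The 4 chemokines had a median of 1.48, with CXCL10 at 4.67 ± 4.72 and 34.2 ± 27.1 FPKM and CX3CL1 at 6.01 ± 2.72 and 27.8 ± 17.2, while CXCL11 differed by 1.01 ± 0.47 (SE) and CXCL8 by 0.79 ± 0.67 (limma adjusted p = 0.804), the latter at 0.18 without LPS+CsA 3. The 5 NF-kB feedback genes had a median of 1.04, with TNFAIP3, the deubiquitinase that ends NF-kB signalling, at 3.09 ± 0.619 and 7.87 ± 4.05 FPKM, BIRC3 at 13.9 ± 2.76 and 41.4 ± 32.4, BCL3 at 19.5 ± 3.16 and 37.2 ± 24.0, and TNFAIP8 at 1.19 ± 1.08 and 3.97 ± 1.66. LPS+CsA 3 carried much of the last groups, with BIRC3 at 78.8 FPKM against 24.4 and 21.1 in LPS+CsA 1 and LPS+CsA 2, and S100A8 there was at 344 FPKM against 129 and 7.90. Without LPS+CsA 3 BIRC3 differed by 0.68 in place of 1.27 and BCL3 by 0.25 in place of 0.73. HBB2 of red blood cells stood at 120.0 ± 10.1 and 235 ± 109 FPKM in LPS and LPS+CsA.

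All members of these 3 lists have a symbol because the authors list them as higher in LPS+CsA than in LPS, so the tests that follow repeat that selection and are not independent evidence of a difference. The 3 lists passed camera with its preset correlation (adjusted p = 0.000410, 0.00337 and 0.000589), and so did the 8 interferon-stimulated genes, all above LPS with a median of 0.82 (adjusted p = 0.0212), of which IRF7, MX2, USP18 and OAS2 are listed by the authors as higher here and all 8 as lower in LPS than in Control. With an estimated correlation none passed, with adjusted p = 0.0549 for the plasma cell, 0.245 for the chemokine, 0.215 for the NF-kB feedback and 0.538 for the interferon list. By fry 1 passed, the plasma cell list (adjusted p = 0.0156). No member was called over all genes tested. Adjusted over the list alone, 3 of the 3 plasma cell genes passed and 0 of the 4 chemokines, of the 5 NF-kB feedback genes and of the 8 interferon-stimulated genes. The chemokine call ended without LPS+CsA 3 (camera adjusted p = 0.0589), and the interferon call ended without LPS 1, LPS 2 or LPS+CsA 1 (0.0777, 0.119 and 0.0849). Among the interferon-stimulated genes MX2 differed by 1.45 ± 0.78 (SE), IRF7 by 1.06 ± 0.80, OAS2 by 1.02 ± 0.78 and IFIT3 by 0.81 ± 0.63. The neutrophil genes had a median of 0.83 (camera adjusted p = 0.457) and the antimicrobial genes, with ACOD1 at 0.91 ± 0.73, DMBT1 at 0.55 ± 0.61 and CHI3L1 at 0.40 ± 0.45, one of 0.81 (0.175). Without LPS+CsA 2 both of these lists passed (0.0219 and 0.00560), whereas without LPS+CsA 3 the neutrophil median turned to -0.15 and the antimicrobial median was 0.14. CHI3L1 turned to -0.02 without LPS+CsA 1, DMBT1 was at 0.08 without LPS+CsA 2 and ACOD1 at 0.41 without LPS+CsA 3. The NF-kB feedback median was 0.68 without LPS+CsA 3.

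The authors' deposited table of this comparison lists 234 genes, 157 higher and 77 lower in LPS+CsA. The highest with a symbol in the authors' deposited table were TMEM200C (8.17, listed at no more than 0.000391 FPKM in the LPS libraries), CXCL10 (2.75), SLC16A14 (2.50), TRAC (2.32) and MZB1 (2.29). The lowest in the authors' deposited table were LSM10 (-3.01), LRRC55 (-2.95), MCIDAS, a driver of multiciliated cell fate (-2.23), ADAMDEC1 (-2.14) and C20orf85 (-2.01). LRRC55 and ADAMDEC1 rested on LPS 1, at 3.88 against 0.416 and 0.365 FPKM and at 91.0 against 16.9 and 22.7, and MCIDAS and C20orf85 on LPS 2, at 1.25 against 0.0977 and 0.255 FPKM and at 25.2 against 1.18 and 7.79. By a Benjamini-Hochberg bound over the 17301 genes at least 26 of the 234 would pass, 19 higher and 7 lower. This lower bound rests on the authors' method and is not like the limma counts. Of the 199 listed genes tested here, 198 had the same sign in limma, 94 an unadjusted p under 0.05 and 0 an adjusted p under 0.05, and the groups of 122 did not overlap.

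The third comparison took CsA alone against Control. Interferon-stimulated genes stood higher in CsA, in CsA 2 and CsA 3 but not in CsA 1. ISG15, a ubiquitin-like antiviral protein chosen after its values were seen, was at 22.3, 212 and 686 FPKM in CsA 1, CsA 2 and CsA 3. In Control it was at 59.1 ± 34.7 (SD, n = 3). IRF7, a transcription factor of the interferon response, was at 15.5, 149 and 252 FPKM in the CsA libraries against 30.0 ± 10.6 in Control. USP18 was at 1.79, 18.9 and 38.7 FPKM, OAS2 at 2.37, 18.5 and 50.2, and IFI44L at 27.6, 142 and 175. The list of 8 had a median log2 difference of 1.17 and passed camera with its preset correlation (adjusted p = 0.00341), not with an estimated correlation (adjusted p = 0.679). The call ended without CsA 3, where the median was 0.45 (adjusted p = 0.406), and without Control 1 (adjusted p = 0.0830); without CsA 1 the median was 2.13. Over all genes tested 0 of the 8 were called, and adjusted over the list alone also 0. The authors list all 8 as lower in LPS than in Control, a choice that favours high Control values.

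Among single genes, NRIP3 stood at 7.55 ± 1.39 FPKM in Control and 2.37 ± 0.607 in CsA (SD, n = 3), KRT82, a hair keratin, at 4.40 ± 1.58 and 1.82 ± 0.646, DLG2, a synaptic scaffold, at 1.52 ± 0.398 and 0.472 ± 0.199, and KANK4 at 3.21 ± 0.723 and 7.16 ± 2.05. TTC39C and ZNF426 on the lower side and EFHD1, TDRD15, MAL and STEAP3, an iron reductase, on the higher side were the other genes with a symbol nearest to the threshold. None passed (limma adjusted p = 0.932 for all 10). CXCL8 differed by 0.10 ± 0.67 (SE; adjusted p = 0.992), with a sign that turned without Control 1, Control 2 or CsA 3 and with array weights. Of the other lists, the plasma cell genes had a median of -0.81, with JCHAIN at -1.33 ± 0.54 and MZB1 at -0.81 ± 0.44, the chemokines -0.18, with CX3CL1 at -0.82 ± 0.76, the NF-kB feedback genes -0.25, with TNFAIP8 at 0.305, 5.96e-06 and 3.00 FPKM in CsA and near 0 in Control, the neutrophil genes 0.92, with S100A8 at 1.12 ± 1.52, and the antimicrobial genes 0.79, with DMBT1 at 1.15 ± 0.61 (SE). None of these 5 passed (camera adjusted p between 0.159 and 0.802). The neutrophil and antimicrobial lists passed without Control 3 (0.0230 and 0.00941), and the antimicrobial and plasma cell lists without CsA 2 (0.0401 for both). Both the neutrophil and the antimicrobial median turned, to -0.09 and -0.17 without CsA 3 and to -0.05 and -0.07 without Control 1, where S100A8 was at -0.01. Without Control 3 the chemokine median turned to 0.64, the NF-kB feedback median to 0.34 and CX3CL1 to 0.22, and the plasma cell median was -0.38, with JCHAIN at -0.69. Without Control 1 the chemokine median was -0.83 and the NF-kB feedback median -0.46. In these 5 lists 0 genes passed adjusted over the list alone.

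Limma called 0 of the 12794 genes, with a smallest adjusted p of 0.292. An unadjusted p under 0.05 was reached by 594 genes, 375 higher and 219 lower in CsA, and by 69 with a change of at least 2-fold. Groups did not overlap for 1207 genes (9.43%, where chance gives 10%). The test recovered 52.2% of 2-fold and 92.5% of 4-fold changes on simulated groups. Without CsA 1 the 594 became 862 and limma called 4 genes, among them TRIM14, at 4.18, 18.6 and 23.9 FPKM in the CsA libraries against 5.64 ± 0.370 in Control, and DDX60, at 1.89, 13.3 and 18.6 against 2.75 ± 1.07 (SD, n = 3); both symbols were singled out after their values were seen, as genes of antiviral defence. Without CsA 2 the 594 genes became 385, and without Control 3 374. Without LPS+CsA 3 limma called 1 gene, ENSOCUG00000009991, which was lower in CsA.

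The comparison of LPS+CsA with Control asked how far animals given both stood from untreated ones. TNFAIP8, an inhibitor of apoptosis, was at 3.05, 2.98 and 5.88 FPKM in LPS+CsA and near 0, at most 5.1e-05 FPKM, in the 3 Control libraries, so that no fold is given. PLLP stood at 3.14 ± 1.13 FPKM in Control and 7.93 ± 1.25 in LPS+CsA (SD, n = 3), GDA, guanine deaminase, at 1.84 ± 0.506 and 6.57 ± 2.40, FEZF2 at 3.87 ± 1.46 and 0.657 ± 0.401, and LSM10 at 9.96 ± 4.76 and 2.39 ± 1.25. FAM83F and ESPN on the higher side and ADAT1, MMP7, a matrix metalloproteinase at 949.6 ± 291 and 374 ± 311 FPKM, and C7orf31 on the lower side were also nearest to the threshold among genes with a symbol. None passed (limma adjusted p = 0.941 for all 10).

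Limma called 0 of the 12794 genes, with a smallest adjusted p of 0.941. An unadjusted p under 0.05 was reached by 617 genes, 457 higher and 160 lower, of which 64 changed at least 2-fold, 47 higher and 17 lower. Without LPS+CsA 3 the 617 became 978 and limma called 1 gene, ENSOCUG00000009991, lower in LPS+CsA. The groups of 1265 genes did not overlap (9.89%, where chance gives 10%). On simulated groups 58.2% of 2-fold and 98.5% of 4-fold changes were recovered. The 5 NF-kB feedback genes stood above Control with a median of 0.98, BCL3 at 0.98 ± 0.36 and BIRC3 at 1.01 ± 0.53 (SE), and passed camera with its preset correlation (adjusted p = 0.000959), not with an estimated correlation (adjusted p = 0.412). Without LPS+CsA 3 the median was 0.43 (adjusted p = 0.295) and without Control 1 0.63 (0.0724). Adjusted over the list alone 1 gene passed, TNFAIP8. Its FPKM switched between near 0 and clearly above it among animals of the LPS group and of the CsA group, so its level is uncertain. The symbols were chosen for high values in these LPS+CsA libraries against LPS, so neither the test nor the count is independent evidence. The chemokines had a median of 1.05 (camera adjusted p = 0.0802, with 0.0447 after median-of-ratios rescaling and 0.0344 after quantile normalization), the interferon-stimulated genes -0.24 (0.142), the plasma cell genes 0.54 (0.142), the neutrophil genes 1.23 (0.244) and the antimicrobial genes 1.19 (0.142). CXCL8 differed by 0.57 ± 0.67 (SE; limma adjusted p = 0.963), a sign that turned to -0.04 without LPS+CsA 3 and to -0.05 with array weights. Without Control 3 the chemokine, neutrophil, antimicrobial and plasma cell lists passed (3.17e-06, 0.0109, 0.00313 and 0.0109). Without LPS+CsA 2 the chemokine, neutrophil and antimicrobial lists passed (0.00721, 0.00721 and 0.00349), and without CsA 1 the interferon list, below Control (0.0214). The neutrophil and antimicrobial medians were 0.26 and 0.28 without LPS+CsA 3 and 0.35 for both without Control 1, where the chemokine median was 0.50. The interferon median was -0.08 without Control 2 and -0.53 without Control 1, and the plasma cell median 0.22 without Control 1, 0.29 without Control 2 and 0.31 without LPS+CsA 2.

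The response to LPS in animals given CsA, LPS+CsA against CsA, shares no library with LPS against Control. TTC39C stood at 4.52 ± 0.709 FPKM in CsA and 9.82 ± 1.68 in LPS+CsA (SD, n = 3), KRT82 at 1.82 ± 0.646 and 5.90 ± 2.05, IGHM, the immunoglobulin mu heavy chain, at 2.11 ± 0.397 and 7.58 ± 4.93, and APOD, a lipid-binding apolipoprotein, at 94.1 ± 62.0 and 262 ± 75.7. These 4 and GDA had a limma adjusted p of 0.696, as did LSM10 on the lower side at 9.18 ± 2.61 and 2.39 ± 1.25 FPKM. IFI44L, USP18, TRIM14 and DDX60 were the other genes with a symbol nearest to the threshold on the lower side, with limma adjusted p between 0.707 and 0.710. Interferon-stimulated genes stood lower in LPS+CsA, with a median of -1.58 and ISG15 at 35.7 ± 9.16 FPKM against 307 ± 342 in CsA, a group whose 3 libraries stood at 22.3, 212 and 686.

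Limma called 0 of the 12794 genes, with a smallest adjusted p of 0.696. An unadjusted p under 0.05 was reached by 892 genes, 536 higher and 356 lower, and by 96 with a change of at least 2-fold; groups did not overlap for 1606 genes (12.6%, where chance gives 10%). Simulated groups gave back 58.2% of 2-fold and 91.0% of 4-fold changes. Without LPS+CsA 1 the 892 became 533, and without CsA 1 limma called 1 gene, ENSOCUG00000029688, at 9.57, 29.4 and 46.1 FPKM in CsA and 8.71 to 11.3 in LPS+CsA, singled out after its values were seen. The interferon list passed camera with its preset correlation (adjusted p = 5.79e-05), as did the NF-kB feedback (median 0.84, adjusted p = 0.000473), plasma cell (1.16, 0.00702) and chemokine (1.28, 0.0150) lists. With an estimated correlation none passed (adjusted p = 0.262, 0.205, 0.205 and 0.291 in the same order). JCHAIN differed by 1.87 ± 0.54 (SE), CX3CL1 by 2.23 ± 0.76, TNFAIP3 by 0.84 ± 0.36 and CXCL8 by 0.47 ± 0.67 (limma adjusted p = 0.875). Adjusted over the list alone, 2 plasma cell genes and 0 of the others passed. The plasma cell, chemokine and NF-kB feedback genes were chosen by the authors for high values in these LPS+CsA libraries against LPS, so their tests and counts are not independent evidence. The plasma cell call ended without CsA 1 or LPS+CsA 2 (0.0552 and 0.0503) and the chemokine call without CsA 1 or LPS+CsA 3 (0.108 and 0.218). The neutrophil and antimicrobial lists, with medians of 0.36 and 0.34, did not pass (0.751 and 0.732), and both turned, to -0.66 and -0.33 without LPS+CsA 3 and to -0.71 and -0.59 without CsA 2. The interferon median was -0.78 without CsA 3 and -2.53 without CsA 1, both past camera (0.0120 and 5.90e-18). The NF-kB feedback median was 0.49 without LPS+CsA 3 and 1.38 without LPS+CsA 2, where the plasma cell median was 0.75. CXCL8 turned to -0.14 without LPS+CsA 3.

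The interaction of the treatments asked whether the effect of CsA differed with LPS. TTC39C gave 1.47 ± 0.25 on the log2 scale (SE; limma adjusted p = 0.517): CsA went with 4.52 ± 0.709 against 7.51 ± 1.74 FPKM in saline-infused animals and with 9.82 ± 1.68 against 4.93 ± 0.652 in LPS-infused ones (SD, n = 3). KRT75 gave 2.82 ± 0.52 (0.563), KRT82 1.95 ± 0.40 (0.792), NRIP3 2.11 ± 0.48 and TUBE1 2.13 ± 0.49 (0.863 for both), and LSM10 -2.43 ± 0.52 (0.815). EFHD1, WNT11, PPP1R1A, a phosphatase inhibitor, and GYG1 were the others with a symbol nearest to the threshold on the lower side, with a limma adjusted p of 0.9997. CXCL8 gave 0.69 ± 0.95 with the same adjusted p, and its sign turned, to -0.08, without Control 3. Limma called 0 of the 12794 genes, with a smallest adjusted p of 0.497. An unadjusted p under 0.05 was reached by 392, where 639.7 would be expected if no gene differed. A 2-fold size as well was reached by 143. Without Control 2 the 392 became 611, and without LPS 1 limma called 1 gene, ENSOCUG00000025431.

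The plasma cell genes gave a median interaction of 2.39, with JCHAIN at 3.21 ± 0.76 and MZB1 at 2.39 ± 0.62 (SE). HBB2 and ALAS2 of red blood cells gave 1.45 ± 0.49 and 1.23 ± 0.39 (limma adjusted p = 1.000 for both). The plasma cell genes passed camera with its preset correlation (adjusted p = 7.57e-06), with an estimated correlation (adjusted p = 0.0191) and in fry (0.0223). The chemokines (median 1.84, CX3CL1 2.78 ± 1.08) and NF-kB feedback genes (median 1.27, TNFAIP3 1.28 ± 0.51) passed with the preset correlation (adjusted p = 0.00113 and 0.000971), not with an estimated correlation (adjusted p = 0.189 for both). Adjusted over the list alone, 2 plasma cell genes, JCHAIN and MZB1, and 0 of the others passed. All members of the 3 lists were listed by the authors as higher in LPS+CsA than in LPS, and JCHAIN, MZB1 and CXCL10 also as lower in LPS than in Control. The interaction holds the same libraries with the same sign, so these tests repeat that selection and do not establish an interaction. Without Control 3 the median was 1.08 for the chemokine list and 0.78 for the NF-kB feedback list, the latter at 0.75 without LPS+CsA 3. The interferon, neutrophil and antimicrobial lists had medians of -0.41, -0.09 and 0.07 and did not pass (0.797, 0.994 and 0.830). Without CsA 1 the interferon list had a median of -1.42 and passed (2.51e-07), while without CsA 3 its median turned to 0.48. The neutrophil and antimicrobial medians were 0.92 and 0.82 without CsA 3 and -1.31 and -0.94 without Control 3.

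Genes that moved in opposite directions in the LPS and CsA steps are the subject of a further deposited table. KRT75 stood at 23.0 ± 7.91, 5.69 ± 0.846 and 22.6 ± 8.52 FPKM in Control, LPS and LPS+CsA (SD, n = 3). The authors' deposited table holds 80 genes, 34 higher then lower and 46 lower then higher. In the authors' deposited table GREM1 (-2.36 then 1.82), CKMT2 (-2.08 then 2.08), SLC5A12 (-2.02 then 1.23), CXCL10 (-1.98 then 2.75) and KRT75 (-1.95 then 1.93) led the lower side, and ZNF770 (4.18 then -1.98), CDC20B (3.27 then -1.92), KCNIP1 (3.00 then -1.99), LRRC55 (2.90 then -2.95) and CPXM2 (2.42 then -1.17) the higher side. By limma 0 genes were called in both steps, and 1, ENSOCUG00000025431, without LPS 1. At an unadjusted p under 0.05 and 2-fold there were 29, 11 higher then lower and 18 lower then higher.

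The LPS libraries enter both steps with opposite sign, so opposite changes arise by chance. Simulated unchanged groups that shared libraries in this way gave a mean of 14.8 such genes, between 6 and 24 in 100 simulations, and independent lists of the same lengths would share 0.390. The fold changes of both steps had a covariance of -0.0692 across genes, against -0.0413 in the simulations. Regroupings of the Control, LPS and LPS+CsA libraries gave a median of -0.0478 and reached -0.0802, beyond the real value. Chance thus cannot be excluded for the covariance. The 3 shared libraries were too few to split, so part of the difference from the simulations can come from them. The LPS responses with and without CsA, which rest on separate animals, had fold changes correlated with Pearson r = 0.236 and Spearman rho = 0.336 across the 12794 genes, which are not independent replicates. Leaving out each library gave a Pearson r of 0.138 to 0.278, and leaving out the 2 libraries of lowest weight 0.0452.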

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

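The tests of other groupings, of scaling, of neutrophil RNA and of exchanged labels were chosen only after the results were seen, while the interaction itself was planned.

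The median interaction of the plasma cell genes (JCHAIN, MZB1 and DERL3) was 2.39 on the log2 scale, which passed camera with its preset correlation (adjusted p = 7.57e-06) and with an estimated correlation (adjusted p = 0.0191). JCHAIN stood at 60.9 ± 51.6 FPKM in Control, 18.9 ± 3.75 in LPS, 21.8 ± 14.6 in CsA and 73.9 ± 22.7 in LPS+CsA (SD, n = 3). The chemokines had a median interaction of 1.84 and the NF-kB feedback genes one of 1.27, both past the preset correlation (adjusted p = 0.00113 and 0.000971) and not past an estimated correlation (adjusted p = 0.189 for both). All members of these 3 lists have a symbol because the authors listed them on these libraries, as higher in LPS+CsA than in LPS, and JCHAIN, MZB1 and CXCL10 also as lower in LPS than in Control. The list tests repeat that selection and do not establish an interaction. Across all genes limma called 0, with 392 at an unadjusted p under 0.05. The libraries were set in 100 groupings, the real one counted. Any grouping reaches the real 0 called genes, so that count cannot test chance, and the highest of the others called 7. With an unadjusted p under 0.05 and a 2-fold size, 55 of 100 groupings gave as many genes as the real 143. The highest of the others gave 526, so chance cannot be excluded for the 143. Nor can it for the 392, which 65 of 100 groupings reached, with 1731 as the highest of the others. The grouping with 526 genes is the highest of those tried, and whether a structure of the samples beyond the 4 groups lies behind it was not tested.

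KRT75 was among genes lower in LPS and higher again in LPS+CsA by value, at 23.0, 5.69 and 22.6 FPKM in Control, LPS and LPS+CsA. By limma 0 genes were called in opposite directions, a count that any regrouping of the 9 libraries reaches, so it cannot test chance. The highest of the regroupings called 2. At an unadjusted p under 0.05 with 2-fold changes there were 29. As many arose in 12 of 100 regroupings, the real grouping counted, the highest with 57, so chance cannot be excluded for the 29. A group of libraries shared by both comparisons could also give the pattern: among the other 11 ways to share a group the highest count was 36. A reversal of the LPS response by CsA stays open as an untested biological explanation.

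Interferon-stimulated genes were high in CsA 2 and CsA 3, with medians of 1.70 and 2.61 against the Control mean, and -0.91 in CsA 1. Scaling between libraries is argued against, since the lower of both medians after rescaling was 1.68, with 0.538 as the highest in Control. RNA from neutrophils is argued against in CsA 2, where S100A8, S100A9 and S100A12 had a median of -1.17. In CsA 3 it was 2.92 and stays open, although LPS+CsA 3 had 3.21 there with an interferon median of -0.62. An exchange of labels stays open, since the highest interferon median outside CsA, 0.578, only restates the pattern. The LPS+CsA animals had the same dose of CsA, and their interferon medians were -0.12, -0.36 and -0.62. With CsA 1 these values argue against a rise in every animal given CsA. An effect of CsA in some animals or only without LPS, or an infection of single animals, may remain, all untested.

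Genes that the authors list as higher in LPS leaned on LPS 1, among them CPXM2 at 45.9, 13.8 and 6.22 FPKM and KCNIP1 at 28.4, 7.32 and 2.18 in LPS 1, LPS 2 and LPS 3. Of the 138 such genes tested, 89 were highest in LPS 1, and 56 had a 2-fold change in limma with all libraries against 42 without LPS 1, 73 without LPS 2 and 83 without LPS 3. Scaling is argued against, since LPS 1 differed from LPS 2 and LPS 3 by a median of 0.026 over all genes tested. The median was 1.18 in the 89 genes highest in LPS 1, which is positive by that choice. A few dominant genes are argued against, with 18.0% of all FPKM in the 10 highest genes of LPS 1, inside the range of the libraries. A larger part of smooth muscle in that sample may be a source and could not be tested, as 0 named members of the smooth muscle list were measured.

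In each pair of groups the 6 libraries allow 10 splits, too few for a share under 0.05; the numbers of splits given here count the real split itself. Limma called 0 genes in the real split of all 5 pairs, a count that any split reaches, so it cannot test chance. The highest of the other splits called 2 each for LPS against Control, LPS+CsA against LPS and LPS+CsA against CsA. It called 1 each for CsA against Control and LPS+CsA against Control. With an unadjusted p under 0.05 and a 2-fold change, the real and the highest other count were 111 and 102 for LPS against Control (1 of 10 splits, the real split itself), 93 and 140 for LPS+CsA against LPS (3), 69 and 147 for CsA against Control (8), 64 and 153 for LPS+CsA against Control (6) and 96 and 251 for LPS+CsA against CsA (6). At an unadjusted p under 0.05 alone they were 839 and 866 for LPS against Control (2 of 10 splits), 1031 and 893 for LPS+CsA against LPS (1, the real split itself), 594 and 1242 for CsA against Control (7), 617 and 1209 for LPS+CsA against Control (4) and 892 and 1480 for LPS+CsA against CsA (4). The splits with 147, 153 and 251 genes lay far above the real counts. They are the highest of the other splits, and whether a structure of the samples other than treatment lies behind them was not tested.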

How the results depend on the processing

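Robust variances, leaving out the 2 libraries of lowest weight (CsA 2 and LPS 1) and the unadjusted threshold were alternatives chosen only after the results were seen. Limma called 0 genes in every comparison. Without a filter, over 17301 genes, it called 2 in LPS against Control, 2 in LPS+CsA against LPS and 2 in opposite directions. On the compared groups alone it called 1 in LPS+CsA against LPS, 1 in LPS+CsA against Control and 1 in LPS+CsA against CsA. Without the 2 libraries of lowest weight it called 1 in LPS against Control, in LPS+CsA against LPS, in the interaction and in opposite directions. With an unadjusted p under 0.05 and 2-fold there were 111, 93, 69, 64 and 96 in the 5 pairs, 143 in the interaction and 29 in opposite directions. Leaving out each library gave 0 to 4 in CsA against Control, 4 without CsA 1, and 0 to 1 in the other comparisons and in opposite directions. The other alternatives called 0. The cause of these changes was not tested.

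The correlation of the LPS responses with and without CsA (Pearson r = 0.236 across genes) was 0.155 with a pseudocount of 0.1, 0.289 with a mean of at least 5 FPKM and 0.0452 without the 2 libraries of lowest weight; leaving out each library gave 0.138 to 0.278. List calls by preset correlation numbered 2, 4, 1, 1, 4 and 3 in the 6 comparisons, by an estimated correlation 0, 0, 0, 0, 0 and 1, and by fry 0, 1, 0, 0, 0 and 1. The chemokine list, LPS+CsA against Control, passed under median-of-ratios rescaling (adjusted p = 0.0447) and quantile normalization (0.0344). The NF-kB feedback list, LPS+CsA against Control, ended at a mean of 5 FPKM (0.0651), and the interferon list without the 2 libraries of lowest weight in CsA against Control (0.0664) and LPS+CsA against LPS (0.104). Of 136 named fold changes 25 changed sign in some alternative, and of 36 list medians 14, none of them a called value. Read depth per library is unknown, which leaves the precision of low FPKM values open.

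Replicate numbers are not said to pair animals. As a hint from the data, 8 of the 18 same-number pairs of libraries had a correlation above 0.1, from -0.0909 to 0.421 (median 0.0852, against -0.0589 for other pairs). The 6 pairs of libraries numbered 3 lay between 0.194 and 0.278, and 9 of the 12 libraries, not all, correlated best with a library of their own number. With the replicate block limma called 0 genes in every comparison, and 994, 1190, 801, 763, 1141 and 467 genes had an unadjusted p under 0.05, against 839, 1031, 594, 617, 892 and 392. The chemokine list, LPS+CsA against Control, passed with the block (camera adjusted p = 0.00269), and no other list call moved.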

Other observations

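The average effects of each treatment, the immunoglobulin loci, FOXJ1, CDC20B, C20orf85 and PPIA, and the term test were chosen only after the results were seen.

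Loci whose annotation by the authors was found to name immunoglobulin, 9 with JCHAIN, moved with the plasma cell genes. IGHM, which the authors list for LPS+CsA against LPS, was not among the 9. By value 9 of 9 were lower in LPS than in Control, with a median log2 difference of -1.30 and 5 at an unadjusted p under 0.05 by limma, and 9 of 9 higher in LPS+CsA than in LPS, with a median of 1.89 and 7 at an unadjusted p under 0.05. None had an adjusted p under 0.05 in limma. In CsA alone 8 of the 9 were below Control, with a median of -1.22. By library the medians against the Control mean were -0.56, -0.43 and 0.85 in Control, -1.29, -1.14 and -1.18 in LPS, -2.11, -0.40 and -0.79 in CsA, and 0.42, 0.51 and 0.20 in LPS+CsA. The loci come from tables chosen on these samples, so they are not independent evidence. Of the 9, the authors list 8 as lower in LPS than in Control and 7 as higher in LPS+CsA than in LPS.

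FOXJ1, CDC20B and C20orf85, chosen after their values were seen, stood highest in LPS 2. FOXJ1 was at 0.538, 11.5 and 2.86 FPKM in LPS 1, LPS 2 and LPS 3, CDC20B at 0.382, 9.98 and 1.60, and C20orf85 at 1.18, 25.2 and 7.79. S100A8, S100A9 and S100A12 of neutrophils had medians of 2.51, 2.92 and 3.21 against the Control mean in Control 3, CsA 3 and LPS+CsA 3 and lay between -1.92 and 1.75 in the other libraries. The locus that the authors name PPIA, the symbol of cyclophilin A, the binding partner of CsA, was listed at 20.9, 25.0 and 22.5 FPKM in LPS. It switched between near 0 and 23.5 FPKM within the CsA group. It also switched among untreated animals, at 0, 101 and 2 reads in Control 1, Control 2 and Control 3, so its level is uncertain.

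A hypothesis was an effect of LPS averaged over the levels of CsA. RASGRF2 then differed by 0.72 ± 0.16 (SE), ZFP62 by 0.63 ± 0.14, APOD by 1.28 ± 0.31, MEDAG by 0.96 ± 0.23 and AGT, the precursor of angiotensin, by 2.19 ± 0.59 (limma adjusted p = 0.364 for each). Limma called 0 genes, with 1443 at an unadjusted p under 0.05; 3 of 100 splits within the levels of CsA, the real one counted, gave as many, with 1869 as the highest of the others. This is 1 of 11 counts that were set against 100 splits or regroupings, all after the results were seen, so it does not settle whether chance gave the 1443. Chance cannot be excluded for the 67 genes with a 2-fold change as well, which 10 of 100 splits reached with 137 as the highest of the others. The 0 called cannot test chance, since any split reaches it. The split with 87 called genes, the highest of the others, set Control 1, LPS 1, LPS 2, CsA 2, LPS+CsA 1 and LPS+CsA 2 against the rest. The 4 libraries numbered 3 stood on one side of it. Whether a structure of the samples other than treatment lies behind it was not tested. For CsA averaged over LPS, LSM10 differed by -1.24 ± 0.26 (SE), TMEM139 by 0.68 ± 0.15 and STEAP3 by 0.81 ± 0.20 (limma adjusted p = 0.433). Limma called 0 genes, with 1344 at an unadjusted p under 0.05, and 8 of 100 splits gave as many, with 1714 as the highest of the others, so chance cannot be excluded. It cannot for the 22 with a 2-fold change, which 85 of 100 splits reached with 106 as the highest of the others. The 0 called again cannot test chance, and the highest of the others called 3.

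Gene ontology terms of the genes listed as higher and lower were compared by Fisher's exact test, two-sided, over terms with at least 5 genes. In LPS against Control 0 of 31 terms passed, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.305. Defense response to virus and antigen binding each had 0 higher and 5 lower genes (exact p = 0.0248 for each), and regulation of transcription, DNA-templated, had 6 higher and 0 lower (exact p = 0.0295). In LPS+CsA against LPS 0 of 24 terms passed, with 1 at an unadjusted p under 0.05 and a smallest adjusted p of 0.416.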
